A study of Mus musculus with 18 samples.

How the data were processed

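The series holds 18 RNA-seq libraries from mouse tissue labelled by depot and genotype: epididymal white fat (eWAT), inguinal white fat (iWAT) and liver, each with 3 libraries labelled KO and 3 labelled WT. Per the labels, KO stands for a floxed Bckdha gene with RIP-Cre and WT for the floxed gene without it, in C57BL/6 mice aged 12 weeks. RIP-Cre commonly names Cre recombinase under the rat insulin promoter, which is active in pancreatic beta cells and some neurons. The sex of the animals is not given in the sources used here. Per the labels' protocols, total RNA was extracted with Trizol, checked on an Agilent instrument, enriched for polyadenylated RNA with oligo(dT) beads, reverse transcribed with random primers and sequenced on an Illumina NovaSeq instrument. Whether the kit marks the strand is not given in the sources used here, so reads of a gene and of an overlapping antisense partner cannot be told apart.

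The submitters' processing notes name fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1, RSEM, DESeq2 and edgeR, and the mouse build mm10; which tool did which step is not given in the sources used here. The authors deposited an expected count and an FPKM value per gene for each library. The deposited expected counts are estimates that need not be whole, and 8.57% of the values were not, each of these at least 0.01 from a whole number. The deposited FPKM values are the authors' own counts scaled by gene length and library size, and were used here only for alternatives. The 22298 gene identifiers are Ensembl identifiers; 22255 matched a symbol in GENCODE M21, 43 did not, and 26 rows whose symbol belonged to a second identifier were kept under the identifier. Coordinates are those of GENCODE M21 on the same build (GRCm38, that is mm10); the authors' annotation release is not given in the sources used here. In all, 2687 genes had no read in any library.

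Expected counts were rounded to whole numbers before testing. Genes were kept by edgeR's filterByExpr rule (minimum count 10, minimum total 15, groups as in the comparison), library sizes were scaled with TMM factors, and genotype was tested within each tissue with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were taken as the absolute fold change divided by the square root of the F statistic. The same test was applied to the difference between the genotype effects of each pair of tissues and to iWAT against eWAT in WT libraries. Values per library are CPM of the TMM-scaled library size, within the 6 libraries of a tissue (for the depots, the 6 WT libraries) unless stated otherwise. Levels of marker genes of other tissues were scaled over all 18 libraries, and the values on reads passing between libraries are CPM of unscaled totals. A gene is called apart when every KO library lies on the same side of every WT library, which chance gives for 10% of genes with 3 libraries against 3.

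Before the data were examined, 54 gene lists were fixed, 30 of pathways and 24 of cell type markers. Lists with at least 3 members past the filter were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a tissue. Camera with the correlation estimated from the libraries and fry (limma) were run beside it. Members of a list were also adjusted over the list alone. The genes named in the text followed a rule fixed at the same time: Bckdha always; the 10 largest rises and falls among genes past the threshold with a mean log2 CPM of at least 1 and groups apart, leaving out predicted genes without a proper symbol and filling up to 5 per direction by lowest p with the statement that they do not pass; and up to 4 members of each list in order of p. For differences between tissues the 5 genes of lowest adjusted p per direction were taken.

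After the data had been seen, further results were added: a genotype effect shared by the tissues, from a fit of tissue plus genotype over 18 libraries, with a replicate block and limma-voom among its alternatives; the list test on the iWAT minus eWAT difference; fits without the eWAT libraries that held abundant epididymal transcripts; and iWAT fits with a B cell score or an inferred batch as a term. Alternatives fixed with the design were other scalings (median-of-ratios, upper quartile), no filter, DESeq2 1.42.0, limma-voom, other dispersion settings, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with and without a minimum mean FPKM of 1, a fit of all 18 libraries together, a replicate block, a minimum absolute log2 fold change of 1 beside the threshold, and leaving out each library in turn.

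Each step was tested on simulated counts drawn from the means, library sizes and dispersions of these libraries, with 200 genes changed 2-fold, 4-fold or 8-fold. Each gene was given its mean over all libraries of the fit. The simulations over several tissues thus held no difference between tissues apart from the changed genes. Their recovery may differ from that in the real libraries, where levels differ between tissues. For 2-fold, 4-fold and 8-fold changes the within-tissue test recovered 0%, 0% and 7.81% in eWAT, 3.03%, 46.0% and 81.8% in iWAT, and 43.9%, 93.8% and 98.4% in liver. The difference between tissues recovered 0%, 12.1% and 40% for iWAT minus eWAT, 0%, 4.55% and 39.1% for liver minus eWAT, and 1.56%, 47.8% and 54.7% for liver minus iWAT. In that order, 2 of 7, 8 of 93, 11 of 162, 2 of 36, 2 of 30 and 2 of 70 calls were false. The depot test recovered 0%, 1.54% and 8.33%, and the shared effect 58.5%, 84.8% and 89.2%, with 1 of 7 and 16 of 168 false calls. Of 10 lists changed 2-fold, the preset correlation recovered 6 in eWAT, 8 in iWAT, 10 in liver and 8 for the iWAT minus eWAT difference. The estimated correlation recovered 0, 7, 6 and 5, and the preset correlation made 0 false calls in each. The simulated genes were drawn independently of each other. These false calls therefore do not test the preset correlation for real lists, whose genes can vary together.

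Total expected counts lay between 16796147 and 28039742 per library. All 18 were used, and no pair of replicates agreed within sampling noise (chi-square per degree of freedom from 33.3 to 1033). Figures were drawn with matplotlib 3.10.9.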

Results

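RNA was profiled in epididymal white fat (eWAT), inguinal white fat (iWAT) and liver of mice that carried a floxed Bckdha gene with RIP-Cre (KO) or without it (WT). No group carried RIP-Cre without the floxed gene, so KO minus WT also holds any effect of RIP-Cre itself. Each of the 6 combinations of tissue and genotype held 3 libraries, 18 in all. Total expected counts ranged from 16796147 to 24357859 in eWAT, from 17959394 to 28039742 in iWAT and from 18629302 to 25969223 in liver, and between 14385 and 18476 genes had reads. The labels do not state that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical in part. All values per gene are CPM (read counts scaled to a common library size) with their SD over n = 3 libraries, and all coordinates are on mm10.

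Bckdha encodes the E1 alpha subunit of the branched-chain ketoacid dehydrogenase complex and lies on chromosome 7 at 25629946 to 25658981. Its level did not differ detectably between the genotypes in any of the 3 tissues. In eWAT it was 207 ± 148 CPM in WT and 137 ± 30.3 in KO (SD, n = 3; log2 fold change -0.59, edgeR quasi-likelihood adjusted p = 0.760). In iWAT it was 184 ± 58.1 and 179 ± 74.1 (log2 fold change -0.04). In liver it was 219 ± 21.6 and 208 ± 31.4 (log2 fold change -0.08, adjusted p = 0.952). The sign of these differences turned positive in each tissue with the deposited FPKM values. The median of all genes shifted with FPKM too, as given below, so in iWAT and liver the turn need not be particular to Bckdha. In eWAT Bckdha moved further than the median, which therefore does not account for the whole turn there. RIP-Cre is commonly active in pancreatic beta cells and some neurons, which were not profiled, so these levels do not check the genotype labels.

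The fat libraries differed in which other tissues' transcripts they held, here in CPM scaled over all 18 libraries. In eWAT, WT replicate 2 held 30810 CPM of Gpx5 and 6335 CPM of Adam7, a pair of genes of the caput epididymis, and 12 CPM of the adipocyte gene Adipoq against 730 to 2797 CPM in the other 5 libraries. Its mean log2 CPM over the mature adipocyte list was 2.78, within the range of the liver libraries (1.54 to 3.04) and against 8.36 to 9.57 in the other eWAT libraries. Gpx5 was the top gene of this library, at 4.39% of its counts. These values argue against it being mainly fat tissue, and every eWAT WT mean (n = 3) includes it. Crisp1, another epididymal gene, reached 760 CPM in WT replicate 2, 1071 in KO replicate 1 and 1238 in KO replicate 3 and at most 1.49 in the other 3. Prm2, a gene of spermatids, stood at 210 CPM in KO replicate 1, 29.4 in WT replicate 2 and at most 3.69 in the other 4. KO replicates 1 and 3 also held 968 and 960 CPM of the smooth muscle gene Myh11. In iWAT, the B cell gene Cd79a stood at 102 to 332 CPM in 5 libraries and at 0.935 in WT replicate 2, which also held 130 CPM of the skeletal muscle gene Acta1. Transcripts of the mitochondrial genome took 15.5% of the counts in eWAT WT replicate 3. In liver, WT replicate 2 stood apart from the other libraries. Its mean log2 CPM was 3.42 over the endothelial list (4.53 to 4.98 in the others) and 2.48 over the hepatic stellate list (3.24 to 3.92).

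**Figure D1:**
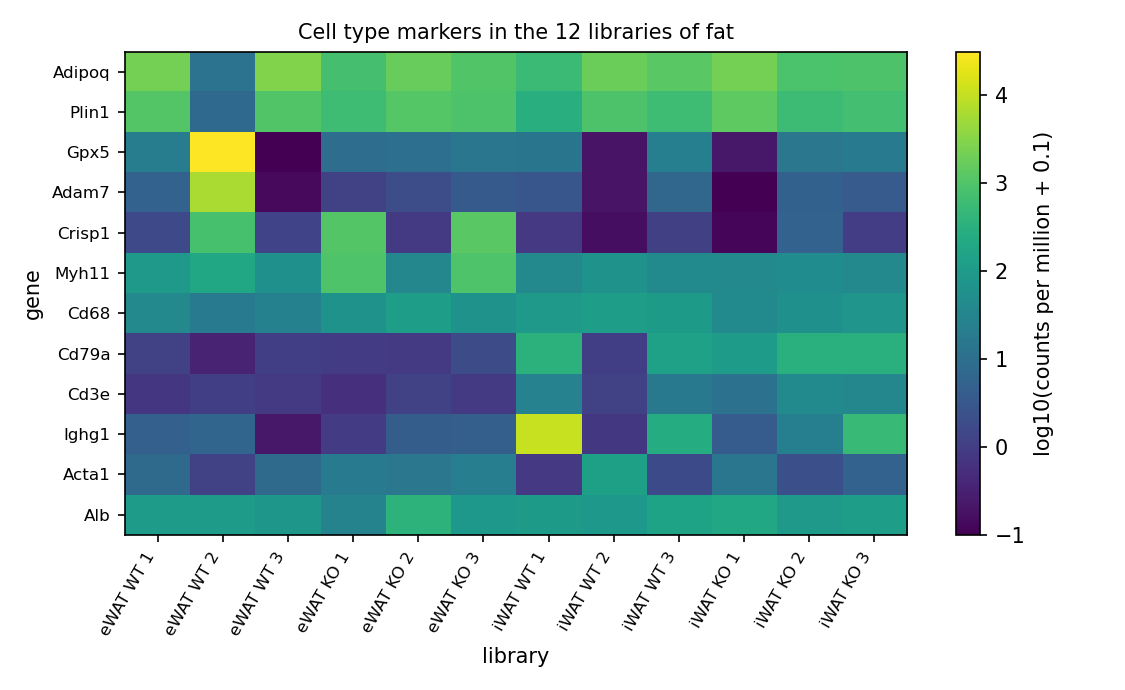
Heat map of log10(CPM + 0.1), scaled over all 18 libraries, of 12 marker genes (rows) in the 12 fat libraries (columns), colour standing for the level. Gpx5, Adam7 and Crisp1 stand out in eWAT WT replicate 2, Crisp1 and Myh11 in eWAT KO replicates 1 and 3, and Cd79a is low in iWAT WT replicate 2.

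The liver comparison asks whether the genotype goes with a different transcriptome in an organ that clears branched-chain ketoacids. In KO liver 4 genes rose and 2 fell. Bcl6, a transcriptional repressor, rose from 3.05 ± 1.31 to 30.6 ± 6.36 CPM (SD, n = 3; log2 fold change 3.31 ± 0.31 SE, edgeR adjusted p = 0.00852; chromosome 16, 23965052 to 23988852). Cish, an inhibitor of cytokine receptor signalling, fell from 23.5 ± 3.71 to 3.82 ± 0.983 CPM (log2 fold change -2.62 ± 0.24, adjusted p = 0.00852; chromosome 9, 107296026 to 107302784). Cyp26a1, which breaks down retinoic acid, fell from 117 ± 15.1 to 27.7 ± 6.81 CPM (log2 fold change -2.08 ± 0.22, adjusted p = 0.0179; chromosome 19, 37697798 to 37701536). Rgs16, a regulator of G protein signalling, rose from 2.91 ± 0.609 to 16.0 ± 5.33 CPM (log2 fold change 2.47 ± 0.30, adjusted p = 0.0321; chromosome 1, 153740349 to 153745468). The inducible heat shock genes Hspa1a (0.706 to 6.09 CPM, log2 fold change 3.08) and Hspa1b (42.7 to 179 CPM, log2 fold change 2.07) also rose (adjusted p = 0.0231 and 0.0321). They lie side by side on chromosome 17 and are near-identical, so the split of reads between them is uncertain. In each of these 6 genes every KO library lay on the same side of every WT library.

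**Figure D2:**
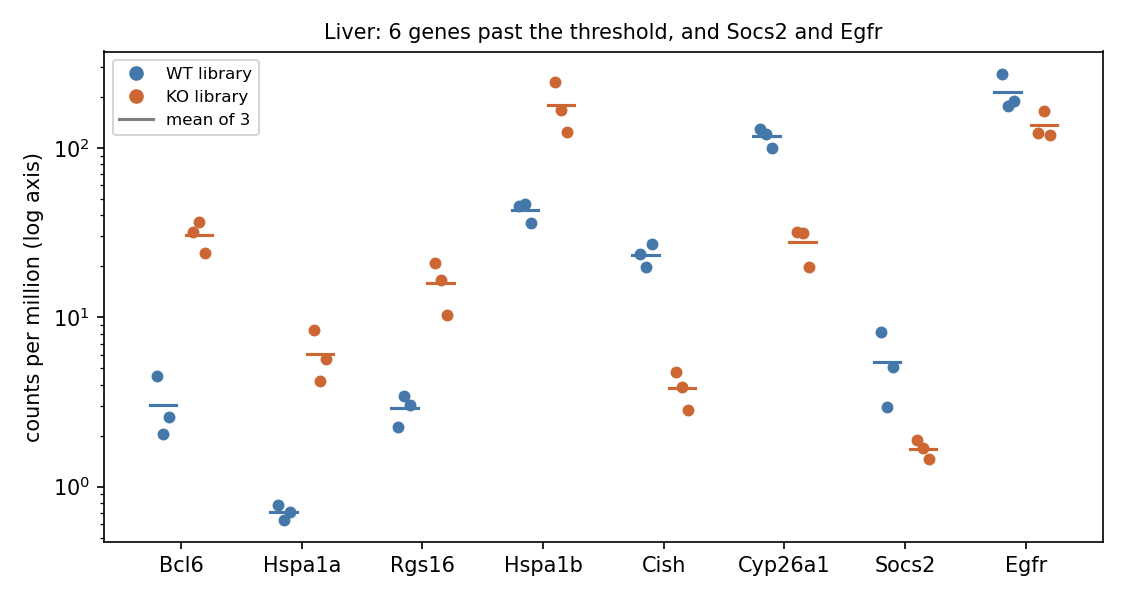
CPM on a log axis of 8 genes in the 6 liver libraries, each point standing for 1 library and each bar for the mean of 3. The KO libraries lie above the WT libraries for Bcl6, Hspa1a, Rgs16 and Hspa1b and below them for Cish, Cyp26a1, Socs2 and Egfr, of which Socs2 and Egfr do not pass the test over all genes.

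These 6 were the calls among 11915 genes tested in liver. DESeq2 called 65, with all 6 among them, and limma-voom 3. At an unadjusted p under 0.05 there were 746 genes, where chance would give 596, and the groups lay apart for 13.0% of genes against 10% by chance. The count depended on single libraries: it was 2 without WT replicate 1, 24 without WT replicate 2, 11 without WT replicate 3, 0 without KO replicate 1 and 2 without KO replicate 2. Of 19 alternatives, the call ended in 2 for Bcl6, 4 for Cish, 5 for Cyp26a1, 7 for Rgs16 and Hspa1b and 8 for Hspa1a. Without KO replicate 1 all 6 ended (adjusted p = 0.141 to 0.21), and in a fit of all 18 libraries all but Bcl6 (Cish 0.775). The count was 2 in that fit and 0 with FPKM and no filter on low values. Without WT replicate 1 the calls left were Bcl6 and Cish. The next genes in order of p did not pass: Ccn2 stood at 3.33 and 10.1 CPM (WT and KO; adjusted p = 0.0604), Cyp2c70 at 476 and 168 (0.0604), Sult5a1 at 8.49 and 2.31 (0.104) and Papss1 at 21.7 and 10.3 (0.139).

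Among the gene lists in liver, those of fatty acid use shifted up in KO. All 17 measured targets of PPAR-alpha were higher, and 5 rose with adjustment over the list alone (camera adjusted p = 3.52e-07 with the preset correlation, adjusted p = 0.493 with an estimated correlation). Among them Acaa1b stood at 347 and 673 CPM, Ehhadh at 235 and 487 and Acot1 at 8.91 and 31.6. The mean log2 CPM of the list was 8.95 and 8.76 in KO replicates 1 and 2 but 7.90 in KO replicate 3, within the WT range (7.77 to 7.95), as was Acot1 there (8.30 CPM; WT 6.76 to 12.8). Of 20 genes of fatty acid beta-oxidation 19 were higher, and 2 rose with adjustment over the list alone (adjusted p = 4.15e-07; 0.493 with an estimated correlation). Acsl1, which activates long-chain fatty acids, stood at 424 and 898 CPM. Lipid synthesis moved the other way: 16 of 18 genes of de novo lipogenesis were lower, and 2 fell with adjustment over the list alone (adjusted p = 6.70e-05; 0.460 with an estimated correlation), with Scd1 at 1391 and 408 CPM and Aacs at 115 and 56.4. Of 24 cholesterol synthesis genes 20 were lower (adjusted p = 1.17e-04; 0.816 with an estimated correlation), a call that ended without KO replicate 3 (adjusted p = 0.0578).

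Secreted and stress-related lists shifted as well in liver. Of 21 acute phase genes 19 were lower, and 6 fell with adjustment over the list alone (adjusted p = 3.52e-07; 0.493 with an estimated correlation), with Orm3 at 10.7 and 2.40 CPM and Apcs at 236 and 84.5. The mean log2 CPM of the list in WT replicate 3 (8.50) lay within the KO range (8.14 to 8.54), against 9.24 and 9.52 in the other WT libraries, and its mean difference went from -0.67 to -0.43 without WT replicate 2. Immediate early genes were higher in 11 of 12, and 4 rose with adjustment over the list alone (adjusted p = 2.14e-06; 0.460 with an estimated correlation), with Fos at 0.914 and 3.83 CPM and Egr1 at 1.84 and 7.41. Of 11 heat shock genes 7 were higher and 3 rose with adjustment over the list alone (adjusted p = 0.00164; 0.493 with an estimated correlation). Growth hormone targets were lower in 6 of 8, and with adjustment over the list alone 5 fell and Bcl6 rose (adjusted p = 0.00418; 0.460 with an estimated correlation); Socs2 stood at 5.42 and 1.68 CPM. The erythroid list was lower in 6 of 6 (adjusted p = 5.95e-05; 0.493 with an estimated correlation), with Hba-a1 at 323 and 145 CPM. The neutrophil list was lower in 7 of 7 (adjusted p = 0.00497; 0.837 with an estimated correlation), a call lost without KO replicate 1, WT replicate 1 or WT replicate 2; S100a8 stood at 6.37 and 11.2 CPM in the latter 2 against 0.188 in WT replicate 3. Also called were the thermogenic (adjusted p = 0.0110) and extracellular matrix lists (0.0332), which were higher, and the oxidative phosphorylation (3.10e-04), glycolysis (0.0162) and epididymis lists (0.0321), which were lower. These 5 lists had an adjusted p of 0.460 to 0.871 with an estimated correlation. The thermogenic list shares Pdk4 with the PPAR-alpha list and Cpt1b with that of beta-oxidation. Its call is therefore not independent of theirs and does not show a separate thermogenic response in liver. The oxidative phosphorylation list reversed without WT replicate 2, the liver library with the lowest endothelial mean. The epididymis list reversed without KO replicate 2, its call also ending without WT replicate 1 or 2. In CPM of unscaled totals, KO replicate 2 held 0 of Gpx5, against 14.2 to 18.9 in the other liver libraries. The epididymis call can thus not be told apart from the low-level reads treated under the other observations. The thermogenic call ended with no filter on low counts and without WT replicates 1 or 2 or KO replicates 1 or 2, the matrix call without WT replicates 2 or 3 or KO replicates 1 or 3, and the glycolysis call without WT replicates 1 or 3 or KO replicate 2. In all, 15 of 49 lists were called in liver with the preset correlation, 6 up and 9 down, and 0 with an estimated correlation or with fry.

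In eWAT no gene passed the test. Among the genes of lowest p, Thbs2, a matricellular protein, stood at 25.1 CPM in WT and 143 CPM in KO (SD 6.03 and 22, n = 3; log2 fold change 2.51 ± 0.25, edgeR adjusted p = 0.508). Synpo2 stood at 26.8 and 222 CPM, Cacna1e at 0.953 and 20.7, Hspb7 at 3.81 and 34.5 and Cotl1 at 30.7 and 130. Elovl6, which elongates fatty acids, stood at 481 ± 262 and 22.6 ± 9.53 CPM (log2 fold change -4.41 ± 0.58, adjusted p = 0.633), and Cyp51, of cholesterol synthesis, at 199 and 57.7. Lactb2 stood at 74.4 and 31.3 CPM, Lss at 50.7 and 18.1 and Pdk1, a kinase that inhibits pyruvate dehydrogenase, at 176 and 63.0. Of 14657 genes edgeR called 0, limma-voom 0 and DESeq2 126, and 1009 had an unadjusted p under 0.05 where chance would give 733. Counted with all 18 libraries in a fit, the calls were 54, and with the 3 libraries without abundant epididymal transcripts, chosen after seeing the data, 33. The latter sets 2 WT libraries against 1 KO library, which is assumed to vary like the WT libraries.

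Lists of lipid synthesis and of mitochondria shifted down in KO eWAT. Of 24 cholesterol synthesis genes 20 were lower, and 9 fell with adjustment over the list alone (camera adjusted p = 4.67e-08; 0.597 with an estimated correlation), with Nsdhl at 99.9 and 25.9 CPM and Idi1 at 91.4 and 37.1. Of 19 genes of de novo lipogenesis 17 were lower, and Elovl6 fell with adjustment over the list alone (adjusted p = 5.58e-04; 0.850 with an estimated correlation), with Acly at 4622 and 627 CPM and Acss2 at 237 and 50.8. All 48 genes of oxidative phosphorylation were lower (adjusted p = 1.65e-12; 0.850 with an estimated correlation; mean log2 fold change -0.90), as were all 13 transcripts of the mitochondrial genome (adjusted p = 4.28e-05; 0.850 with an estimated correlation). The list of branched-chain amino acid catabolism was lower in 24 of 27 (adjusted p = 0.00106; 0.850 with an estimated correlation), with Acad8 at 58.5 and 36.0 CPM, and that of the TCA cycle in 19 of 20 (adjusted p = 8.63e-04; 0.850 with an estimated correlation). Without WT replicate 3, the library with the high mitochondrial share, the mean log2 difference went from -0.73 to -0.25 for oxidative phosphorylation, from -1.05 to -0.29 for the mitochondrial genome and from -0.98 to -0.39 for de novo lipogenesis. The branched-chain list had a mean difference of -0.41 with all libraries and 0.0026 without WT replicate 3, and the TCA cycle list -0.68 and -0.14. Neither was called without it (adjusted p = 0.379 and 0.28) or without WT replicate 1 (0.0540 and 0.055). WT replicate 2 scored below every KO library in 4 of these lists, with oxidative phosphorylation at 5.72 on the log2 scale against 5.90 to 6.07 in KO and 7.52 in WT replicate 3.

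Lists of matrix and immune cells shifted up in KO eWAT. Extracellular matrix genes were higher in 21 of 23 (adjusted p = 2.79e-07; 0.850 with an estimated correlation), with Fbn1 at 57.6 and 227 CPM and Bgn at 243 and 493. Macrophage genes were higher in 12 of 12 (adjusted p = 8.19e-06; 0.850 with an estimated correlation), with Cd68 at 38.7 and 112 CPM, and inflammatory mediators in 14 of 14 (adjusted p = 4.28e-05; 0.850 with an estimated correlation). The mean log2 CPM of inflammatory mediators was 3.38 in KO replicate 2, but 1.36 and 1.18 in KO replicates 1 and 3. Their mean difference was 1.75 with the main settings and 1.13 to 2.85 over the alternatives. Ptgs2 stood at 1028 CPM in KO replicate 1, 7.23 in KO replicate 2 and 1422 in KO replicate 3, the first and the last being the libraries that held Crisp1 and Myh11. Immediate early genes were higher in 12 of 14 (adjusted p = 8.19e-06; 0.850 with an estimated correlation) and cell division genes in 18 of 18 (adjusted p = 1.96e-05; 0.850 with an estimated correlation). The latter had a mean log2 CPM of 1.68 in KO replicate 1, the library with the most Prm2, and 0.589 and 0.145 in the other KO libraries, and their mean difference went from 0.97 to 0.55 without it. Smooth muscle genes were higher in 7 of 8 (adjusted p = 0.0454; 0.850 with an estimated correlation), a call that ended without any 1 of 5 libraries (all but KO replicate 2), with a reversed sign in the 3 libraries without abundant epididymal transcripts. Without WT replicate 2, the library with little Adipoq, the mean difference went from 1.26 to 0.79 for matrix and from 1.3 to 0.78 for macrophage genes. T cell (adjusted p = 2.89e-04), pancreatic acinar (0.00898), plasma cell (0.00971) and interferon genes (0.0260) were higher on balance as well (each 0.850 with an estimated correlation). The latter 3 were not called without KO replicate 2, plasma cell genes not without WT replicate 3 and interferon genes not without WT replicate 2. In CPM of unscaled totals, WT replicate 3 held 0.128 of the plasma cell gene Ighg1, against 1.44 to 8.75 in the other eWAT libraries. The plasma cell call can thus not be told apart from the low-level reads treated under the other observations. The adipokine list was called up (adjusted p = 0.0454; 0.850 with an estimated correlation) with a mean fitted log2 fold change of 0.58 and a median of -0.14, and a mean difference of 1.5 on the log2 CPM scale of the test, a call that ended without KO replicate 2 and turned down without WT replicate 2. In all, 17 of 54 lists were called, 11 up and 6 down, 30 without KO replicate 1, and 0 with an estimated correlation or with fry.

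**Figure D3:**
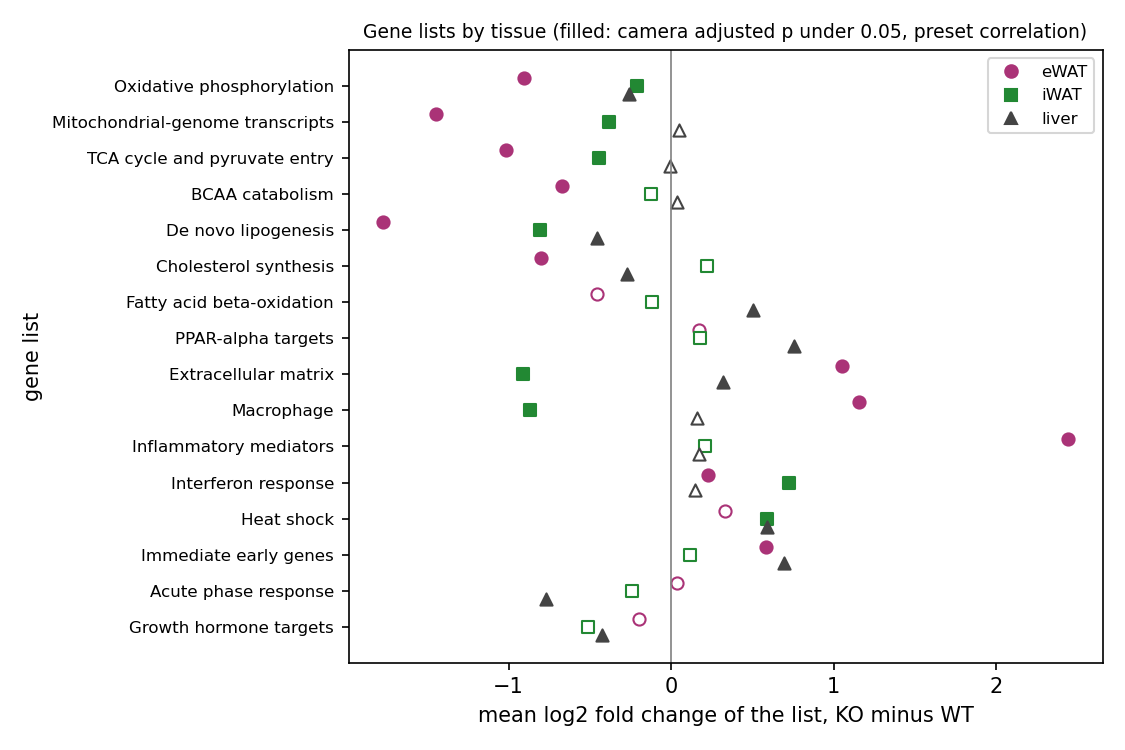
Mean log2 fold change (KO minus WT) of 16 gene lists in the 3 tissues, each point standing for 1 list in 1 tissue and filled where the camera adjusted p with the preset correlation is under 0.05. De novo lipogenesis lies below 0 in all 3 tissues, while macrophage and extracellular matrix lists lie above 0 in eWAT and below 0 in iWAT.

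In iWAT no gene passed the test either. The major urinary protein genes Mup22 (1827 ± 748 in WT and 101 ± 37.9 CPM in KO; SD, n = 3; log2 fold change -4.17 ± 0.47, edgeR adjusted p = 0.917) and Mup18 (629 and 37.1) had the lowest p among genes lower in KO, and belong to a family of near-identical copies whose reads may be split. Cish stood at 48.7 ± 21.4 and 7.74 ± 0.725 CPM, Clec4a2 at 20.5 and 9.67 and Ccr1 at 13.9 and 4.22. On the other side, Ddit4, an inhibitor of mTORC1, stood at 29.8 and 57.1 CPM, Fam20c at 21.6 and 91.0, Oasl1 at 6.44 and 19.5 and Dnajb1 at 58.1 and 121. Of 14226 genes edgeR called 0, limma-voom 0 and DESeq2 67, and 630 had an unadjusted p under 0.05 where chance would give 711. With an inferred batch as a term, chosen after seeing the data, there were 2 calls.

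Lists in KO iWAT shifted up for interferon and down for macrophages, matrix and lipid synthesis. Interferon response genes were higher in 20 of 21 (camera adjusted p = 5.10e-10; 0.895 with an estimated correlation), with Irf7 at 60.3 and 152 CPM and Xaf1 at 10.6 and 19.8. Macrophage genes were lower in 12 of 12, and 5 fell with adjustment over the list alone (adjusted p = 6.79e-11; 0.895 with an estimated correlation), with Mrc1 at 283 and 115 CPM and Adgre1 at 113 and 56.6. Extracellular matrix genes were lower in 21 of 23 (adjusted p = 8.35e-09; 0.895 with an estimated correlation), with Lum at 168 and 44.3 CPM and Col3a1 at 1640 and 442. De novo lipogenesis was lower in 17 of 18 (adjusted p = 4.34e-08; 0.895 with an estimated correlation), with Elovl6 at 424 and 113 CPM. The TCA cycle (adjusted p = 6.11e-06) and mitochondrial genome (2.06e-05) lists were lower too (each 0.895 with an estimated correlation). So were the oxidative phosphorylation (5.66e-05), glycolysis (9.46e-04) and erythroid lists (0.00266), but not without KO replicate 2 nor, for the first 2, with a B cell score as a term, and heat shock genes were higher (0.00198), but not without WT replicate 1 or KO replicate 1. Each of these 4 had an adjusted p of 0.895 with an estimated correlation. T cell (10 of 10; adjusted p = 0.00266) and B cell genes (11 of 11; 0.00512) were higher (both 0.895 with an estimated correlation), calls that ended without WT replicate 2, the library with little Cd79a. Without that library the B cell mean difference turned from 2.26 to -0.11 and the T cell one fell from 1.97 to 0.19. The mean difference of the matrix list went from -0.79 to -0.40 without it, and without KO replicate 2 that of de novo lipogenesis from -0.79 to -0.38. In all, 12 of 53 lists were called, 4 up and 8 down, and 0 with an estimated correlation or with fry. The count was 20 without WT replicate 1, 24 without WT replicate 2, 20 without WT replicate 3 and 19 without KO replicate 3. Splitting the 6 iWAT libraries 3 against 3 in the 9 other ways gave more calls each time, 16 to 30. The number of calls thus does not set genotype apart from other groupings of these libraries.

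Whether the genotype differences depend on the tissue was tested as a difference of differences. No gene passed for iWAT minus eWAT (0 of 15455 by edgeR, 858 at an unadjusted p under 0.05, 30 by DESeq2), for liver minus eWAT (0 of 14984, 876 and 39) or for liver minus iWAT (0 of 14673, 681 and 35). The lowest adjusted p was 0.149, shared by Rgs16 and Mup18 for liver minus iWAT. Without the 3 eWAT libraries that held epididymal transcripts the counts were 2 for iWAT minus eWAT and 62 for liver minus eWAT. For liver minus eWAT it was 1 without the libraries of WT replicate 3 and 2 without those of KO replicate 2. Among lists, a test chosen after seeing the data called 14 of 54 for iWAT minus eWAT, 4 up and 10 down. Macrophage (mean log2 difference -2.15, camera adjusted p = 3.84e-14) and extracellular matrix genes (-2.09, 1.21e-17) were among the 10, and cholesterol synthesis (0.85, 1.38e-11) among the 4. With an estimated correlation the lowest adjusted p was 0.388. Without the libraries of WT replicate 2 the macrophage difference was -1.4 and the matrix difference -1.2.

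A genotype effect shared by the 3 tissues was also fitted, chosen after seeing the data. Bcl6 rose (log2 fold change 2.32 ± 0.31 SE, edgeR adjusted p = 0.00963) and Cish fell (-2.42 ± 0.33, 0.00963). Bcl6 stood at 16.6 and 85.2 CPM in eWAT and 34.9 and 92.6 in iWAT, and Cish at 44.6 and 11.2 in eWAT. The fit tests the mean genotype effect over all 18 libraries, among them those of liver, where both genes had already passed. Within the fat depots neither passed (edgeR adjusted p = 0.633 in eWAT and 0.9997 in iWAT for both). No alternative left out the liver as a whole, so the calls do not show an effect in each tissue. Arl15 fell (-0.75), and Dtx3l (1.16), Prr32 (3.36), Banp (0.79) and the co-chaperone gene Dnajb1 (0.74) rose, making 7 calls among 15717 genes. Elovl6 did not pass (-2.42, adjusted p = 0.0850). If the tissues came from the same animals these p-values may be too small. With genotype and number as a random block the correlation was -0.041, which bears on this only if the numbers mark animals. The count was 3 without eWAT WT replicate 1, 28 without eWAT WT replicate 2, 17 without eWAT KO replicate 2, 4 without iWAT WT replicate 2, 3 without iWAT WT replicate 3, 4 without iWAT KO replicate 1 and 11 without liver KO replicate 2. Of 24 alternatives, Bcl6 was called in 24, Cish and Arl15 in 23, Dtx3l in 20, Prr32 in 17, Banp in 15 and Dnajb1 in 8. The alternative without a call of Cish was limma-voom (adjusted p = 0.066), which made 16 calls.

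**Figure D4:**
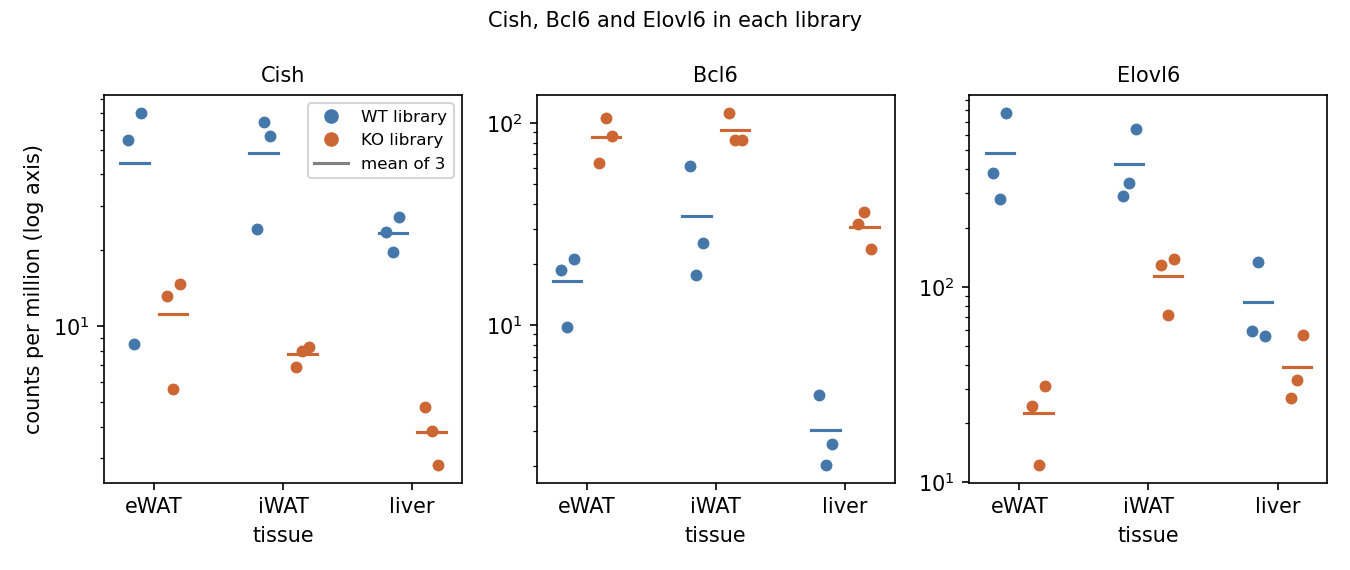
CPM on a log axis of Cish, Bcl6 and Elovl6 in each library of the 3 tissues, by genotype, each point standing for 1 library and each bar for the mean of 3. Cish is lower on average and Bcl6 higher in KO in each tissue, with overlap of single libraries for Cish in eWAT.

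The fat depots were compared in WT libraries, as a check on the tissue labels. Tbx15, a developmental gene of subcutaneous fat, stood at 16.0, 36.3 and 24.8 CPM in the iWAT libraries and at most at 0.0472 in those of eWAT. Tcf21, a developmental gene of visceral fat, stood at 8.40, 14.0 and 3.25 CPM in eWAT and at most at 0.0501 in iWAT. Over the whole visceral list the mean log2 CPM was 2.18 and 1.02 in eWAT WT replicates 1 and 3 but -0.33 in WT replicate 2. It was -1.65 to -1.10 in the iWAT WT libraries. As eWAT WT replicate 2 held little Adipoq and much epididymal RNA, its Tcf21 does not show that it is fat. Of 14006 genes edgeR called 0 (2276 at an unadjusted p under 0.05), and DESeq2 called 1166. Without iWAT WT replicate 2 there were 315 calls, without eWAT WT replicate 3 there were 17, and without eWAT WT replicate 2 there were 3.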

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

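All tests of explanations in this part were chosen after the results had been seen; the counts over other splits of the libraries were planned before those splits were run.

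A pair of gene lists differed between the fat depots in their response to genotype. The extracellular matrix list had a mean log2 difference of -2.09 for iWAT minus eWAT, and the macrophage list one of -2.15: both were higher in KO eWAT and lower in KO iWAT. Without the libraries of WT replicate 2, of which that of eWAT held little adipocyte RNA, they were -1.2 and -1.4. With an estimated correlation neither passed (adjusted p = 0.388 for both). The test called 14 lists with the real labels and up to 33 with other splits of the libraries; 9 of the 10 splits, the real one included, gave at least 14, and 10 splits are too few for a share under 0.05.

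The list shifts in eWAT were set against the epididymal transcripts in 3 of its 6 libraries. Of the 6 lists called down, WT replicate 2 lay under the mean of the KO libraries by more than 2 SD in 4, which argues against its epididymal RNA as the cause of those 4 shifts. Of the 11 called up, 8 stayed called without it, but with the preset correlation alone and with smaller means for matrix (1.26 to 0.79) and macrophages (1.3 to 0.78), so for these it stays open. These 2 tests replaced an earlier one over all 17 lists, of which 14 stayed called without WT replicate 2. The 3 libraries without abundant epididymal transcripts also gave 14 of the 17, and a mean log2 difference of -1.26 for smooth muscle, but they set 2 WT libraries against KO replicate 2 alone and called 31 lists, so they decide neither whether epididymal RNA in KO replicates 1 and 3 sets the shifts nor whether it sets the smooth muscle rise. A response of fat to the genotype stays open and untested. For the 17 lists, 8 of 10 splits, the real one included, gave as many, with up to 29 in another split.

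The 6 libraries of a tissue can be split in 10 ways, the real one included, too few for a share under 0.05. For genes the real count and the highest other count were 0 and 8 in eWAT (10 splits gave as many, the real one counted here and below), 0 and 464 in iWAT (10) and 6 and 2 in liver (1). The eWAT split with 8 calls set WT replicates 1 and 3 and KO replicate 2, the libraries without abundant epididymal transcripts, against the rest. The iWAT split with 464 calls set WT replicate 1 and KO replicates 2 and 3 against the rest, which points to a structure of the samples other than genotype. Those libraries had the highest mean log2 CPM over the B cell list (7.40 to 7.55, against -0.08 to 6.40 in the rest). Their T cell means were the highest too (5.66 to 6.23, against 0.015 to 5.01). The split thus follows B and T cell content, though whether this gave the 464 calls was not tested. An inferred batch that puts WT replicate 2 and KO replicate 1 together is a different grouping. These are the iWAT libraries with almost none of the low-level caput reads treated under the other observations. In eWAT only WT replicate 3 and in liver only KO replicate 2 were like them, so there the grouping falls within a single genotype. With the inferred batch as a term the iWAT genotype test gave 2 calls. For lists the real count and the highest other count were 12 and 30 in iWAT (10) and 15 and 16 in liver (2). In iWAT the real count of lists was the lowest of the 10 splits. For differences between tissues they were 0 and 26 for iWAT minus eWAT, 0 and 23 for liver minus eWAT and 0 and 0 for liver minus iWAT, and for the depots in WT 0 and 0 (10 in each). For the shared genotype effect 9 of 60 splits, the real one included, gave at least 7 calls, with up to 114 in another split, so chance is not excluded.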

How the results depend on the processing

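Alternatives added after seeing the data are the fits without epididymal libraries, those with a B cell score or inferred batch, and all for the shared effect and the list difference. Counts depended on the tool: DESeq2 called 126 genes in eWAT, 67 in iWAT, 65 in liver, 30, 39 and 35 for iWAT minus eWAT, liver minus eWAT and liver minus iWAT, and 1166 between depots. In liver limma-voom called 3, FPKM without a filter 0 and a fit of all 18 libraries 2; in eWAT that fit called 54. With an estimated correlation or fry, 0 lists were called in each tissue and for the list difference. The 3 eWAT libraries without epididymal transcripts gave 33 genes and 31 lists, and leaving the others out gave 2 genes for iWAT minus eWAT and 62 for liver minus eWAT. In iWAT the inferred batch gave 2 genes and the B cell score 24 lists. The cause of these changes was not tested.

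Leaving out single libraries gave 0 to 24 genes in liver, 16 to 30 lists in eWAT, 15 to 24 lists in iWAT, 0 to 2 genes for liver minus eWAT, 0 to 315 between depots and 3 to 28 for the shared effect. Bckdha turned positive with FPKM and a pseudocount of 1 or 0.1 (0.095 and 0.10 in eWAT, 0.048 and 0.048 in iWAT, 0.023 and 0.023 in liver), with the B cell score in iWAT (0.223), and without a library (leave-outs -1.04 to 0.060 in eWAT, -0.39 to 0.19 in iWAT, -0.20 to 0.020 in liver). FPKM moved the median of all genes by 0.306, 0.360 and 0.203 on the log2 scale in eWAT, 0.119 and 0.139 in iWAT and 0.109 in liver. Lists that reversed without a library, with the range of their mean log2 difference over such fits, were interferon (-0.029 to 0.85) and adipokines (0.037 to 2.30, the test turning down) in eWAT, B cell in iWAT (-0.11 to 3.73), oxidative phosphorylation (-0.39 to 0.054) and epididymis (-2.0 to 0.12) in liver, and for the list difference adipokines (-2.66 to 0.45), B cell (-0.24 to 2.96), endothelial (-1.71 to 0.23) and mitochondrial genome (-0.079 to 1.18). Without the epididymal libraries smooth muscle reversed in eWAT (-1.26) and in the difference (1.24), and hepatic stellate (0.32) in the difference.

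Same-numbered libraries did not deviate together, so a replicate block pairs numbers only. With that block the liver had 30 calls, and lists 22, 17 and 17 in eWAT, iWAT and liver and 11 for the difference. For the shared effect a block of replicate number gave 4 calls, with Bcl6, Cish and Arl15 among them. limma-voom gave 16, and 22 with genotype and number as a random replicate block, whose correlation was -0.041. Over all alternatives, single genes kept their direction and side of the threshold in 2193 cases, passed it newly in 135, no longer passed in 71 and reversed in 16. Most of these genes did not pass with the main settings, and staying under the threshold counts as kept, so the 2193 do not measure how firm the calls were. The 71 fell on the genes called with the main settings, 6 in liver and 7 for the shared effect. Lists called with the main settings kept their direction and call in 489 cases, no longer passed in 192 and reversed in 12. Genes under 1 CPM, such as Hspa1a in WT liver, rest on few reads, so counting error adds to their spread.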

Other observations

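Single genes of other lists stood apart in KO liver. With adjustment over the list alone Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose (109 ± 16.6 to 200 ± 43.7 CPM; SD, n = 3), and Asns, an asparagine synthetase induced by amino acid shortage, fell (15.9 ± 4.16 to 3.46 ± 2.73). Neither passed over all genes. Across the 3 tissues 11485 genes were tested; 16 lay higher in every KO library in each tissue and 5 lower. Chance would give 1.44 in each direction with 10% of genes apart per tissue, and 2.42 and 3.47 with the shares seen in each tissue, in both cases only if the tissues vary independently, which shared animals would break.

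All tests from here on were chosen after the results had been seen. Low levels of the caput epididymis genes appeared outside eWAT WT replicate 2. In 13 of the 17 other libraries 6 such genes summed to between 0.0323% and 0.0806% of their level there, and in 4 (eWAT WT replicate 3, iWAT WT replicate 2, iWAT KO replicate 1 and liver KO replicate 2) to at most 9.04e-04%. In CPM of the unscaled library totals Ighg1, abundant in iWAT WT replicate 1 (15130), was at most 0.193 in the eWAT and liver libraries without these reads and 1.44 to 13.4 in those with them (exact one-sided rank p = 0.0182). This is consistent with reads or RNA passing between libraries handled or sequenced together. Carry-over of tissue at dissection cannot be told apart from it by the profile of 6 genes (r = 0.995 across genes), since either source gives that profile.

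Cish was lower and Bcl6 higher in KO in the 3 tissues, and 3 explanations were weighed. An effect of the RIP-Cre transgene itself was not among them and cannot be told apart from loss of Bckdha, as no group carried RIP-Cre alone. Lower growth hormone signalling in liver stays open: 5 of the 6 other targets of the list were lower, and 4 passed with adjustment over the list alone, but the bound was set with the result of the list known, so meeting it decides nothing. A different feeding state stays open: 4 of 5 lists shifted in liver in the direction known for fasting, but these 4 were picked after their shifts were seen. The other, gluconeogenesis, did not shift (7 of 14 higher, median log2 fold change -0.016). Lep, which fasting lowers, stood at 725, 8.05 and 273 CPM in WT and 868 to 1371 in KO eWAT, and at 85.7 to 392 and 339 to 989 in iWAT, without passing. The 8.05 is WT replicate 2, with little Adipoq; without it the eWAT log2 fold change went from 1.78 to 1.2. Collection at different times of day stays open. The evening minus morning clock gene difference (KO minus WT) was 0.34 ± 0.13 (SE) in eWAT, 0.41 ± 0.16 in iWAT and 0.80 ± 0.10 in liver on the log2 scale, more than 2 standard errors from 0 and the same way in 3 tissues. The bound for this test was rewritten 2 times after the values were seen: the earlier ones, among them under 0.5 in at least 2 tissues, would have excluded the explanation, but a shift of a few hours could stay under them. The difference lay under 1, the size set for a large time difference, in each tissue, and an effect of genotype or feeding on the clock cannot be told apart from collection time here.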
